A study of Homo sapiens with 12 samples.

How the data were processed

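The data are 12 arrays (Affymetrix Human Genome U133 Plus 2.0) of IGROV-1 cells in 4 groups of 3: Parental, Mock (scrambled shRNA, a pool of clones) and the CXCR4 shRNA clones shCXCR4_I and shCXCR4_II. Per the labels, the Mock and shCXCR4 cells were transfected with a lipid reagent and selected with 4 µg/ml puromycin for 30 days, and Parental cells were not. In all groups 6 µg of total RNA per array was labelled as biotinylated cRNA. The authors deposited one log2 value per probe set and array, made with RMA in R 2.6.0 per their processing notes. The chip definition file, the background step and any filter are not given in the sources used here. The values run from about 1 to 13 with nearly equal medians, as log2 values do. Their scale was not checked against scanner files, which are not used here. No further normalization was applied.

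The platform annotation lists 54675 probe sets, of which 41097 carry 1 gene symbol, 1801 several and 11777 none, and 62 are controls. By Entrez gene number, 41043 probe sets matched the gene name table used here, and 0 symbols needed updating. Each gene was represented by the single-symbol probe set with the highest mean over the 12 arrays, which gave 19775 genes. No coordinates were used.

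Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group-means model on all 12 arrays, 8 residual and 5.19 prior degrees of freedom), at a Benjamini-Hochberg adjusted p under 0.05, and those changed at least 2-fold were also counted. The contrasts were each line against Mock, Mock against Parental, line I against line II, and each line against Parental. The mean of both lines against Mock was also tested, and its gene list counts are given. Errors of fold changes are limma's standard errors. No replicate block was used, since the labels state no batch behind the replicate numbers. For the 3 CXCR4 probe sets, p was adjusted over all single-symbol probe sets, except for 217028_at, which represents the gene and takes its p from the test of all genes. A total of 27 gene lists with 673 genes, set by pathway, cell process or cell type, were fixed before the data were examined, and 619 of these genes were measured. Lists were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast, and again with an estimated correlation. The test fry was run as well. It asks whether a list's genes move one way on balance and does not compare a list with other genes.

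Genes to be named were set by a rule fixed before the data were examined. They are CXCR4 and a panel of 10 others. To these come the 10 genes up and 10 down with the largest smaller change in the lines, past the test in both and with every array of both lines beyond every Mock array. The rule adds the 8 up and 8 down with the largest change in each of the 4 comparisons, with no overlap of arrays. From each list it takes up to 3 members past the test in both lines and the largest member in each comparison. The rule named 164 genes. LPAR3 as the single 2-fold lower gene and PTTG1 as the single mitotic gene up in line II fall under the rule as well.

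Because both lines share the Mock arrays, 100 simulated data sets without any change gave the correlation and covariance that array noise in the shared arrays produces alone. These data sets held no difference between groups, so a shift of the Mock pool is not part of them. The overlap was also counted with separate controls. On simulated data with 50 changed genes of each size among 19775, line I against Mock recovered 44% at 1.25-fold, 94% at 1.5-fold and 100% at 2-fold, and called 12 of 19550 unchanged genes. Line II against Mock recovered 42%, 92% and 100% and called 8 unchanged genes, and both lines together recovered 32%, 90% and 100%. Far fewer genes changed in the simulation than passed in the data, where the cutoff on p is looser. These shares and numbers of false calls therefore do not carry over to the data. The alternatives tried were all probe sets, the mean of a gene's probe sets, leaving out probe sets named _x_at or _s_at, 2 filters on dim genes, quantile normalization, centring of arrays, a trended and robust variance, array weights, a fit of only the groups compared, a replicate block, a minimum fold of 1.2, adjusted p under 0.01, Parental or both controls in place of Mock for the gene counts of each line, and leaving out each array in turn. Replacing Mock by Parental was planned for the gene counts only. For the gene lists it was added after the data were seen. For named genes the signs against Parental are given as counts. Figures were drawn with Python 3.11.15, matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6.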

Results

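RNA levels were measured on Affymetrix Human Genome U133 Plus 2.0 arrays in IGROV-1, an established human ovarian cancer cell line, after stable knockdown of CXCR4, the receptor for the chemokine CXCL12. The 12 arrays form 4 groups of 3. Parental cells were not transfected, and Mock cells are a pool of clones that carry a scrambled short hairpin RNA (shRNA). Line I (shCXCR4_I) and line II (shCXCR4_II) are individual clones, each with a different shRNA sequence against CXCR4. The comparisons ask which transcripts depend on CXCR4 in these cells. Because the controls are a pool and the knockdown lines are clones, knockdown and clonal origin change together in every comparison with Mock. The median log2 value over probe sets lay between 4.25 and 4.39 on the 12 arrays. The interquartile range was 3.38 to 3.43 on the Mock arrays and 3.19 to 3.31 on the others. Pearson correlations across probe sets within a group were 0.996 to 0.998. The root mean square log2 difference between group means was smallest between lines I and II, at 0.166, and largest between Mock and line II, at 0.273. The difference between Mock and Parental was 0.225. The number of arrays limits the precision, and the p-values measure only the spread between these arrays, which may be technical. Genes are given by symbol, with the probe set where a single one matters.

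CXCR4 fell in both knockdown lines. On probe set 217028_at (Entrez gene 7852), the log2 value was 8.33 ± 0.07 in Parental, 8.58 ± 0.07 in Mock, 7.09 ± 0.02 in line I and 6.62 ± 0.20 in line II (mean ± SD, n = 3 arrays each). The log2 fold change against Mock was -1.49 in line I (SE 0.09, limma adjusted p = 6.11e-08), which leaves 35.6% of the Mock level. In line II it was -1.96 (SE 0.09, limma adjusted p = 4.38e-09), which leaves 25.7%. All 3 arrays of each line lay below all 3 Mock arrays. On 209201_x_at the fold changes were -1.12 and -1.38, and on 211919_s_at they were -1.07 and -1.24. CXCR4 was 0.47 higher in line I than in line II on 217028_at (limma adjusted p = 0.00517). That difference was 0.26 on 209201_x_at (limma adjusted p = 0.262) and 0.17 on 211919_s_at (limma adjusted p = 0.463), so it passed the test on 1 of the 3 probe sets. Mock exceeded Parental by 0.25 on 217028_at, which did not pass (limma adjusted p = 0.0699). It passed on 211919_s_at, at 0.36 (limma adjusted p = 0.0465), but not when p was adjusted over all probe sets of the array (0.0558).

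**Figure D1:**
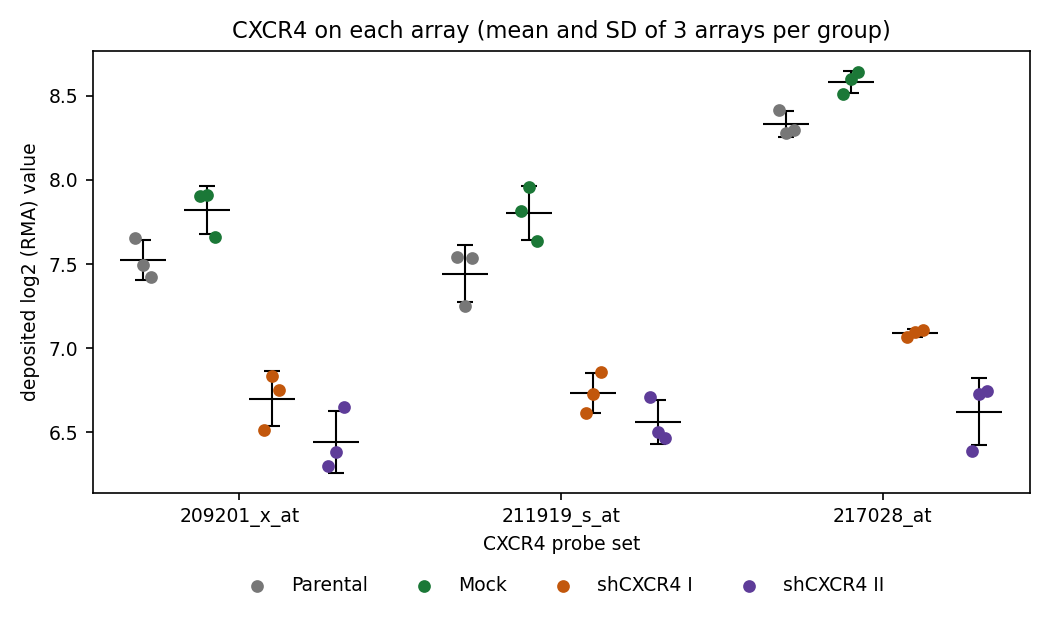
Deposited log2 value of CXCR4 on each of the 12 arrays (vertical axis) for its 3 probe sets (horizontal axis), with points for arrays and bars for the group mean and SD of 3 arrays. On 217028_at the group means are 8.33 in Parental, 8.58 in Mock, 7.09 in line I and 6.62 in line II.

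Of the panel of genes around CXCR4 signalling that was set before the data were examined, IL6 and JAG1 fell in both lines. IL6, a cytokine, had log2 fold changes of -0.77 in line I (SE 0.09, limma adjusted p = 3.87e-05) and -0.69 in line II (SE 0.09, limma adjusted p = 0.000124). JAG1, a Notch ligand, had -0.45 and -0.43 (SE 0.06 each, limma adjusted p = 0.000227 and 0.00036). Both genes were also lower against Parental in each line, IL6 by -0.85 and -0.77 and JAG1 by -0.28 and -0.27. CXCL8 rose in line I alone, by 1.60 (SE 0.06, limma adjusted p = 9.04e-10), against -0.03 in line II, and the difference between the lines passed its own test at 1.63 (limma adjusted p = 8.01e-09). VEGFA fell by 0.31 in line II (limma adjusted p = 0.00751) and had -0.14 in line I. The VEGFA call ended under quantile normalization, at -0.18 (limma adjusted p = 0.0826), and with the mean of its probe sets, at -0.003. TNF rose by 0.35 in line I (limma adjusted p = 0.0204). This call ended after centring each array on its median (adjusted p = 0.0581), without line I replicate 1 (0.0718) or 3 (0.0501) and without Mock replicate 1 (0.077) or 2 (0.0553). The ligand CXCL12 (0.11 and 0.15), ACKR3 (0.17 and 0.13), CCL2 (0.11 and 0.06), NOTCH3 (0.24 and 0.18) and HES1 (0.25 and -0.08) did not pass in lines I and II. The list of 16 measured CXCR4-axis genes had 1 gene up and 3 down in line I and 1 up and 2 down in line II, with the same counts adjusted over the list alone. Its median was 0.01 in line I and 0.04 in line II, its mean was -0.10 and -0.14, and limma's camera gave a downward sign with adjusted p = 0.502 and 0.698.

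The genes past the test in the same direction in both lines against Mock are changes that the 2 clones share relative to the Mock pool. A change of Mock alone would enter this set too. Of its 2925 genes, 1472 passed against Parental in that direction in neither line. The largest falls were in DACH1, a transcriptional regulator, with -4.41 in line I and -4.31 in line II (SE 0.08 each, limma adjusted p = 2.23e-12 and 3.01e-12, n = 3 arrays per group), and in GJA1, which encodes the gap junction protein connexin 43, with -4.27 and -3.96 (SE 0.09 each, limma adjusted p = 2.35e-12 and 6.32e-12). The largest rises included IL32, a cytokine, with 2.56 and 2.47 (SE 0.11 each, limma adjusted p = 3.68e-09 and 4.74e-09), and UNC93A with 3.04 and 2.27 (SE 0.14 each). The serine synthesis enzyme PHGDH rose by 1.90 and 1.75, the matrix protein NPNT by 1.90 and 1.75, the adhesion molecule NRCAM by 2.32 and 2.21, and BCL2L15 by 2.43 and 2.79. SAMD5 (2.03 and 2.47), LINC00518 (1.87 and 1.99), SYTL2 (2.07 and 1.80) and CREB5 (1.70 and 1.48) complete the 10 leading rises. The other leading falls were EEF1A2 (-3.63 and -3.29), TOX3 (-3.26 and -3.28), LRCH2 (-3.22 and -2.96), NCALD (-2.96 and -3.20), BASP1 (-2.93 and -2.94), NOSTRIN (-2.58 and -2.79), THSD7A (-2.52 and -3.73) and EYA4 (-2.64 and -2.46). NCALD no longer passed in line II, at -0.23 (limma adjusted p = 0.0586), when probe sets named _x_at or _s_at were left out. Some of these genes lay below the array medians of 4.25 to 4.39 in the lower of the groups compared. The mean log2 values in lines I and II were 2.6 and 2.7 for DACH1, 2.94 and 3.25 for GJA1, 2.36 and 2.61 for LRCH2, 3.67 and 3.66 for BASP1, 2.95 and 2.73 for NOSTRIN and 2.86 and 3.04 for EYA4, and 3.67 in line II for THSD7A. In Mock they were 3.89 for UNC93A, 2.96 for LINC00518 and 3.65 for CREB5. No background level is given in the sources used here. The fold changes of such genes, in every comparison, therefore describe the deposited values, and neither their exact size nor their rank among the largest is settled.

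In all, 2925 genes were shared, 1105 up and 1820 down, of which 94 changed at least 2-fold in both lines, 31 up and 63 down. The count of 94 was 62 with the mean of a gene's probe sets, and 46 at a mean log2 of at least 6 and 62 in the upper 50% by mean log2, which test fewer genes. Opposite calls in the lines were made for 37 genes. After quantile normalization 55.5% of the shared genes were up, and after centring each array on its median 17.8%, against 37.8% as deposited, so the split by direction is not fixed by these data. Quantile normalization kept 1773 of the 2925 genes, and it kept all 94 of the 2-fold genes past the test. Independent lists of these sizes would share 217.3 genes up and 407.8 down, but both lists use the same Mock arrays. The log2 fold changes of the lines correlated across genes at r = 0.809, where simulated lines without any change gave 0.4996 from the shared arrays alone. The covariance was 0.0586 against a simulated 0.00401. The simulation held array noise and no shift of the Mock pool, so the excess over it can include such a shift. Where the controls were separate, the correlation was 0.42 for line I against Mock and line II against Parental. It was 0.415 for line II against Mock and line I against Parental. The covariances were then 0.028 and 0.0277. With separate controls, line I against Mock and line II against Parental shared 1326 genes, 469 up and 857 down, where 147.4 and 255.8 would be independent, and 275 were opposite. Line II against Mock and line I against Parental shared 1355, 439 up and 916 down, where 179.8 and 255.9 would be independent, and 304 were opposite. Genes are not independent replicates.

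**Figure D2:**
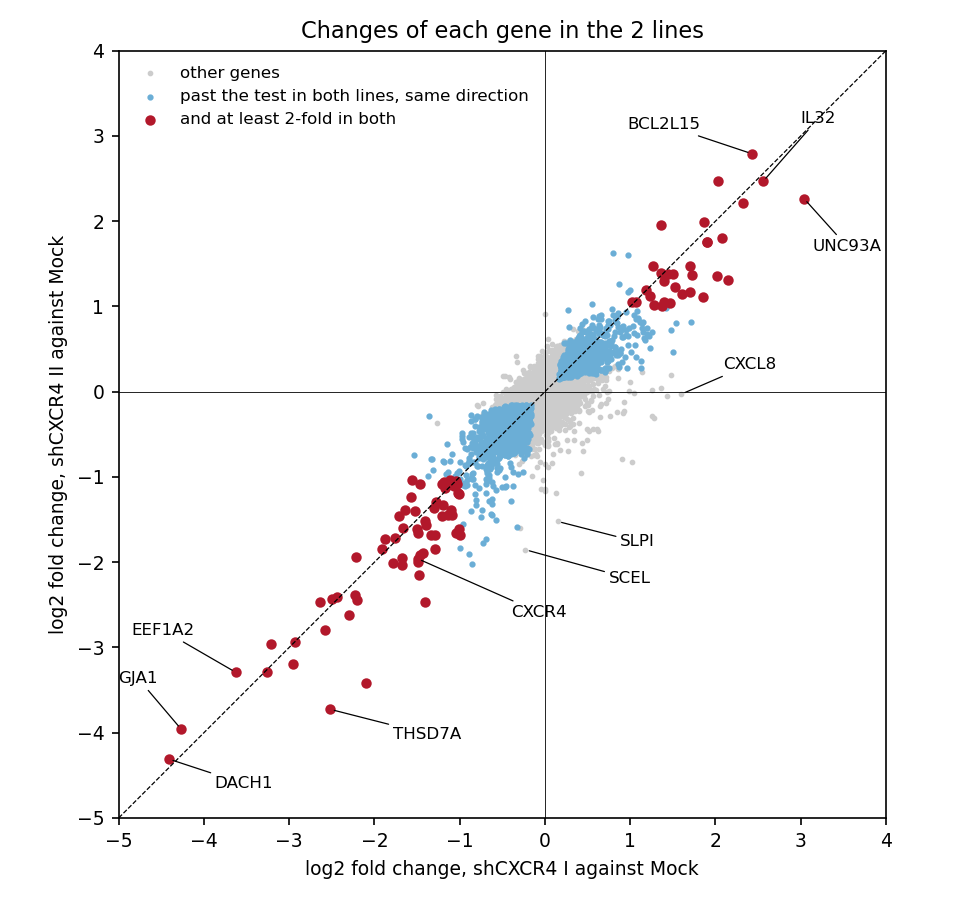
Log2 fold change of each of 19775 genes in line I (horizontal axis) and line II (vertical axis), both against Mock, with the line of equal change dashed. Blue points are genes past the test in the same direction in both lines and red points the 94 that also changed at least 2-fold, while CXCL8, SLPI and SCEL lie off the line.

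The comparison with both controls asks which of these changes do not depend on the choice of control. Among the leading genes, GJA1 was lower against Parental too, by -5.17 in line I and -4.86 in line II (SE 0.09 each) on the deposited values, which lay below the array medians in both lines, as were DACH1 (-2.91 and -2.81), BASP1 (-2.48 and -2.49), THSD7A (-1.91 and -3.12) and CXCR4 (-1.24 and -1.71). IL32 (1.86 and 1.77), NPNT (2.23 and 2.09), LINC00518 (1.58 and 1.71) and the aldehyde dehydrogenase ALDH1A3 (2.04 and 1.98) were higher against Parental too. Past the test against Parental in both lines, by less than against Mock, were also EEF1A2 (-1.02 and -0.69), TOX3 (-1.30 and -1.32), EYA4 (-1.51 and -1.34), NCALD (-2.57 and -2.81), PHGDH (1.03 and 0.88), UNC93A (2.04 and 1.26), NRCAM (0.56 and 0.46) and SAMD5 (0.54 and 0.97). NOSTRIN had -0.13 (limma adjusted p = 0.444) and -0.35 (0.0302), and SYTL2 had 0.41 (0.0044) and 0.14 (0.289). LRCH2 (-0.06 and 0.19) and CREB5 (0.20 and -0.02) passed in neither line. BCL2L15 was lower against Parental in line I, at -0.38 (limma adjusted p = 0.00271), and had -0.01 in line II. In total 907 genes passed in the same direction in all 4 contrasts, 293 up and 614 down, and 35 of them were at least 2-fold in all 4, 6 up and 29 down. The count of 35 was 18 with the mean of a gene's probe sets, and 12 at a mean log2 of at least 6 and 20 in the upper 50%, which test fewer genes. The count of 907 was 568 without _x_at and _s_at probe sets. The share up was 32.3% as deposited, 54.1% after quantile normalization and 19.6% after centring. Of the 2925 shared genes, 1472 passed against Parental in their shared direction in neither line. Of the 94 genes changed at least 2-fold, 71 passed in that direction in all 4 contrasts and 13 did so against Parental in neither line. Among the named genes past the test in line I against Mock, 29 of 135 had the other sign against Parental, and in line II 26 did. In line I, 16 of these passed against Parental in that other direction. They were BCL2L15 (-0.38), SHISA3 (1.66), CRACDL (0.25), KIT (-2.13), NIBAN1 (-1.67), PNOC (-1.64), ITGB8 (-0.72), CAV2 (-0.44), KCNJ16 (-0.45), MFAP2 (-0.35), RGS2 (0.38), TNFAIP3 (-0.37), MAML2 (-0.36), POLE2 (0.26), CDH1 (-0.59) and SPRY2 (0.27). In line II the 12 such genes were SHISA3 (1.95), KIT (-2.15), NIBAN1 (-1.47), PNOC (-1.24), ITGB8 (-1.14), CAV2 (-0.56), CKB (0.46), SYBU (-0.53), RRM2 (0.22), TGFA (-0.64), ID3 (0.52) and PRAME (0.36).

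**Figure D3:**
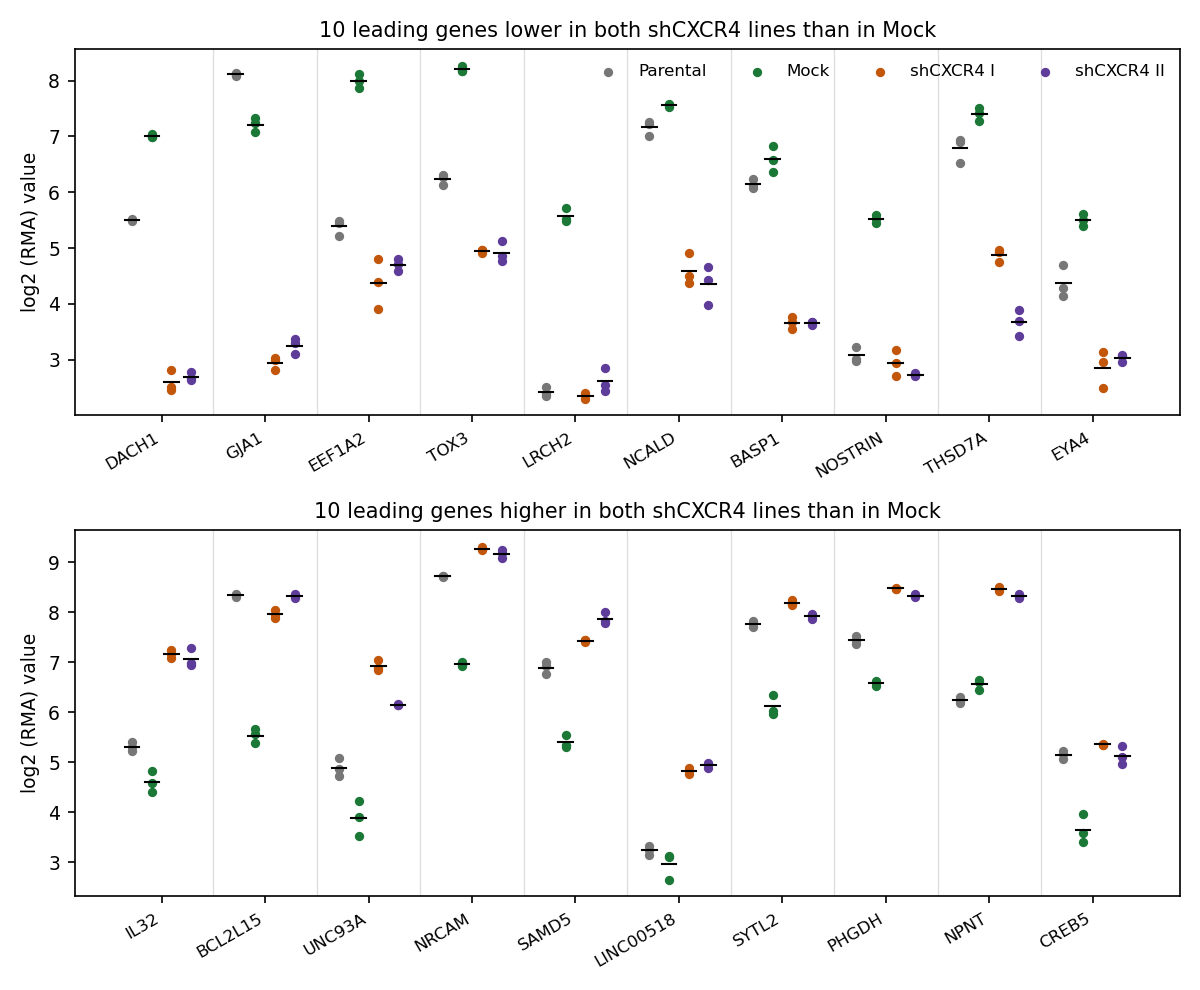
Log2 value on each array (points) and group mean (bars) of the 10 genes that fell most and the 10 that rose most in both lines against Mock, for Parental, Mock, line I and line II. GJA1 lies at 8.11 in Parental and 7.21 in Mock against 2.94 in line I and 3.25 in line II, while BCL2L15 lies at 8.34 in Parental and 5.53 in Mock.

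Line I against Mock gave 4670 genes past the test, 1972 up and 2698 down, and 151 changed at least 2-fold, 71 up and 80 down. The count of 151 was 95 with the mean of a gene's probe sets and 75 at a mean log2 of at least 6. Mitotic genes fell: CENPE, a kinetochore motor, by -0.85 (SE 0.07, limma adjusted p = 2.96e-06), NUSAP1 by -0.78 (SE 0.07, limma adjusted p = 7.58e-06), CDCA8 by -0.72 and KIF11 by -0.64 (n = 3 arrays per group). Of 30 mitotic cell cycle genes none rose and 29 fell, also adjusted over the list alone, with a median of -0.58 (limma's camera adjusted p = 3.69e-24, and adjusted p = 0.0126 with an estimated correlation). Of 30 DNA replication genes 21 fell and none rose, 24 adjusted over the list alone, with a median of -0.31 (camera adjusted p = 1.95e-13, and adjusted p = 0.00949 with an estimated correlation). RRM2 led that list at -0.59. The lectin LGALS3 rose by 2.15, against 1.32 in line II, and SCGB2A1 by 2.02, against 1.35. For LGALS3 the call rests on its _s_at probe set, since it was 0.11 (limma adjusted p = 0.455) in line I and 0.11 (0.453) in line II without such probe sets.

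Among invasion and adhesion genes in line I, 13 of 35 rose and 1 fell, with 13 and 2 adjusted over the list alone (camera adjusted p = 0.00321, and adjusted p = 0.104 with an estimated correlation). They included the integrins ITGB8 (1.46, but -0.72 against Parental) and ITGA5 (1.07), the protease PLAU (1.44) and NCAM1 (1.26). Among inflammatory cytokines and chemokines 6 of 25 rose and 1 fell, the same counts adjusted over the list alone (camera adjusted p = 0.0151, and adjusted p = 0.104 with an estimated correlation), led by CXCL8 (1.60) and CXCL1 (1.27). Of 25 unfolded protein and integrated stress response genes, 11 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.00785, and adjusted p = 0.295 with an estimated correlation). PHGDH (1.90), ASNS (1.53) and TRIB3 (0.63) rose, although ASNS was 0.10 (limma adjusted p = 0.4) without _x_at and _s_at probe sets. The median of this list was 0.05 and turned to -0.02 after centring. Of 18 cholesterol synthesis genes 8 fell and 1 rose, with 10 and 1 adjusted over the list alone (camera adjusted p = 0.00712, and adjusted p = 0.104 with an estimated correlation). Of 16 RNA interference machinery genes 6 fell and none rose, 7 adjusted over the list alone, including TNRC6A (-0.50), DROSHA (-0.36) and DICER1 (-0.30), with camera adjusted p = 0.00785, and adjusted p = 0.104 with an estimated correlation. With the mean of a gene's probe sets TNRC6A was -0.12 (limma adjusted p = 0.118) and DICER1 -0.05 (0.579). Quantile normalization ended the calls for DROSHA, at -0.26 (limma adjusted p = 0.0608), and DICER1, at -0.20 (0.0872). The DICER1 call also ended without line I replicate 3 (0.0933) or Mock replicate 3 (0.0716). Of 16 leukocyte markers 4 rose and none fell, the same adjusted over the list alone, with CD3E at 0.39 and ITGAM at 0.37 (camera adjusted p = 0.0468, and adjusted p = 0.115 with an estimated correlation). The CD3E call ended without line I replicate 1 (limma adjusted p = 0.0618) or 3 (0.0537) or Mock replicate 2 (0.0668). The ITGAM call ended without any one of the line I replicates (0.059, 0.0967 and 0.117 in order) or without Mock replicate 2 (0.0782) or 3 (0.156). It also ended under quantile normalization (0.0949), centring (0.0758) and a fit of only the groups compared (0.0645). Of 31 hypoxia and glycolysis genes 10 fell and 4 rose, with 12 and 4 adjusted over the list alone (camera adjusted p = 0.0473, and adjusted p = 0.276 with an estimated correlation), and NDRG1 rose by 0.92 while PDK1 fell by 0.49. PDK1 was -0.16 (limma adjusted p = 0.0915) with the mean of its probe sets.

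After quantile normalization 53.7% of the genes past the test in line I were up, and after centring 23.8%, against 42.2% as deposited. Quantile normalization ended the list calls for inflammatory (adjusted p = 0.0758), cholesterol (0.0758), RNA interference (0.0616), leukocyte (0.292) and hypoxia genes (0.173). Leaving out _x_at and _s_at probe sets ended the inflammatory (0.107), hypoxia (0.109), cholesterol (0.0774) and leukocyte calls (0.107), and the mean of a gene's probe sets ended the hypoxia (0.0925) and leukocyte calls (0.0925). With the trended and robust variance the leukocyte call ended (0.0601). Both filters on dim genes, which test fewer genes, ended the hypoxia, cholesterol and RNA interference calls, at 0.801, 0.282 and 0.181 for a mean log2 of at least 6 and 0.629, 0.138 and 0.111 in the upper 50%. A list left with under 5 genes was not tested, so a call not named here, such as the leukocyte one, did not necessarily hold under these filters. The hypoxia call also ended without line I replicate 1 (adjusted p = 0.0687) or 3 (0.0654) and without Mock replicate 1 (0.0594) or 2 (0.0842), and the leukocyte call without line I replicate 1 (0.0751) or 3 (0.0566) or Mock replicate 2 (0.0842), all by camera.

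**Figure D4:**
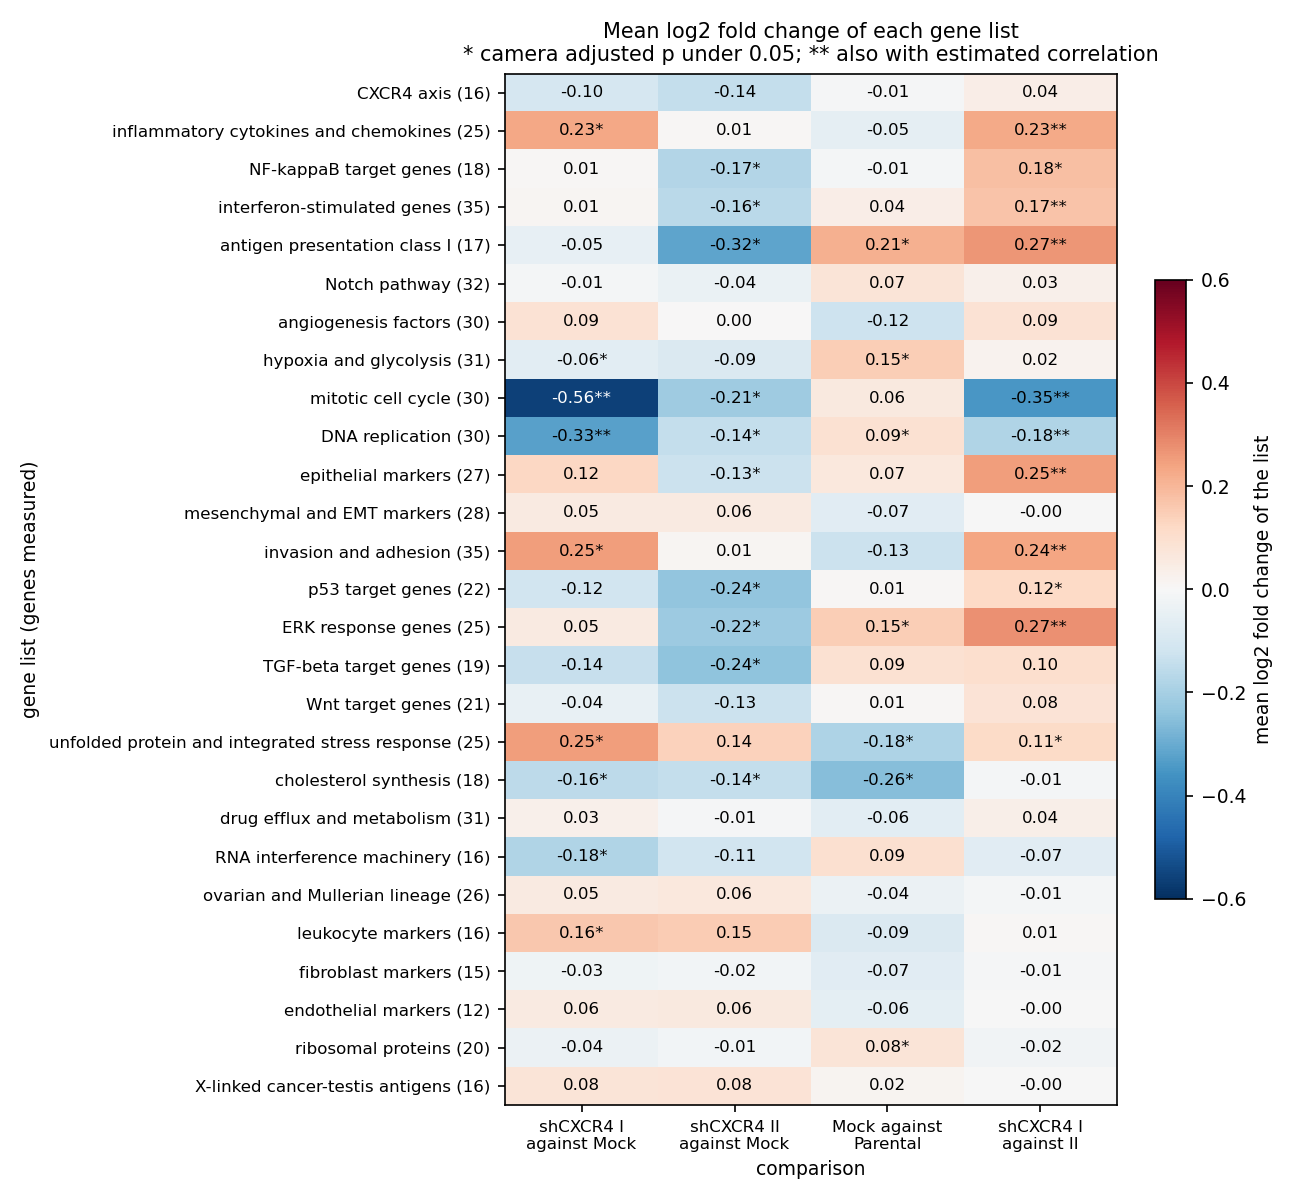
Mean log2 fold change of each of the 27 gene lists (vertical axis, with the number of genes measured) in 4 comparisons (horizontal axis), with a star for camera adjusted p under 0.05 and a second star where it also passed with an estimated correlation. The mitotic list has -0.56 in line I and -0.21 in line II against Mock, and -0.35 in line I against line II.

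Line II against Mock gave 5168 genes past the test, 2179 up and 2989 down, and 152 changed at least 2-fold, 37 up and 115 down. The count of 152 was 101 with the mean of a gene's probe sets and 78 at a mean log2 of at least 6, and that of 5168 was 3027 in a fit of only the groups compared. KCTD12 had a log2 fold change of -3.41 (SE 0.08, limma adjusted p = 1.38e-11), against -2.10 in line I, and the transcription factor SOX9 one of -2.47 (SE 0.08, limma adjusted p = 1.92e-10), against -1.41 in line I (n = 3 arrays per group). STK32B rose by 1.96 (SE 0.07, limma adjusted p = 4.31e-10), against 1.36 in line I. SLPI (-1.52) and SCEL (-1.85) fell in this line and did not pass in line I. Of 17 class I antigen presentation genes 12 fell and none rose, with 12 and 1 adjusted over the list alone, led by the immunoproteasome subunit PSMB9 at -1.20 (median -0.26, camera adjusted p = 1.21e-05, and adjusted p = 0.142 with an estimated correlation). Of 30 mitotic genes 14 fell and 1, PTTG1, rose, with 18 and 1 adjusted over the list alone (median -0.28, camera adjusted p = 8.62e-06, and adjusted p = 0.142 with an estimated correlation). CENPE (-0.49), KIF11 (-0.48) and NUSAP1 (-0.46) fell. Of 30 DNA replication genes 10 fell and none rose, 12 adjusted over the list alone (camera adjusted p = 0.000418, and adjusted p = 0.135 with an estimated correlation). Of 22 p53 target genes 10 fell and none rose, with 12 and 1 adjusted over the list alone, RRM2B by -0.80 (camera adjusted p = 0.000273, and adjusted p = 0.142 with an estimated correlation).

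Interferon-stimulated genes in line II had 15 of 35 down and 1 up, with 16 and 2 adjusted over the list alone (camera adjusted p = 0.00126, and adjusted p = 0.0999 with an estimated correlation), and IFITM1 (-0.67) and OAS3 (-0.63) fell. Of 25 ERK response genes 13 fell and 4 rose, with 15 and 5 adjusted over the list alone (camera adjusted p = 0.00298, and adjusted p = 0.142 with an estimated correlation). PHLDA1 (-1.19) and SPRY2 (-1.11) fell, and TGFA rose by 0.66. Of 19 TGF-beta target genes 8 fell and 1 rose, the same adjusted over the list alone, with SKIL at -1.61 (camera adjusted p = 0.00455, and adjusted p = 0.13 with an estimated correlation). Of 18 NF-kappaB target genes 7 fell and none rose, the same adjusted over the list alone, with NFKB2 at -0.56 (camera adjusted p = 0.00917, and adjusted p = 0.142 with an estimated correlation). Of 18 cholesterol synthesis genes 7 fell and 1 rose, with 9 and 1 adjusted over the list alone (camera adjusted p = 0.0168, and adjusted p = 0.142 with an estimated correlation). Of 27 epithelial markers 10 fell and 2 rose, with 11 and 3 adjusted over the list alone, and CDH1, which encodes E-cadherin, fell by 0.69 (camera adjusted p = 0.0358, and adjusted p = 0.142 with an estimated correlation). Of genes past the test in line II, 42.2% were up as deposited, 54.6% after quantile normalization and 21.3% after centring. Quantile normalization ended the calls for DNA replication (camera adjusted p = 0.187), NF-kappaB (0.0694), cholesterol (0.318) and epithelial genes (0.169). Leaving out _x_at and _s_at probe sets ended the NF-kappaB (0.17), TGF-beta (0.17) and epithelial calls (0.281), and the mean of a gene's probe sets ended the epithelial call (0.0544). A mean log2 of at least 6, which tests fewer genes, ended the calls for NF-kappaB (0.134), interferon-stimulated (0.0825), DNA replication (0.144), epithelial (0.284), p53 (0.119), ERK response (0.119) and cholesterol genes (0.327). The upper 50% by mean log2 ended the same calls (0.147, 0.0852, 0.318, 0.0603, 0.0564 and 0.287 in that order) other than the interferon one. The epithelial call also ended without line II replicate 3 (0.0622) or Mock replicate 3 (0.0604).

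Camera was also run on each line against Parental, a comparison of lists chosen after the data were seen. In line I the mitotic (median -0.52, camera adjusted p = 5.62e-28), DNA replication (-0.26, 2.6e-10) and cholesterol lists (-0.45, 9.65e-10) were lower against Parental as well, each past camera with an estimated correlation too (adjusted p = 0.00768 for all 3). Part of the cholesterol fall against Parental was already present in Mock, since the list mean was -0.256 in Mock against Parental and -0.156 in line I against Mock. The line I calls against Mock on lists other than these 3 were not made against Parental. Invasion and adhesion genes had 9 up and 4 down, the same adjusted over the list alone (camera adjusted p = 0.194). Hypoxia and glycolysis genes had 7 up and 2 down, with 9 and 2 adjusted over the list alone, a median of 0.01 and an upward camera sign that did not pass (adjusted p = 0.295, and adjusted p = 0.516 with an estimated correlation). The adjusted p was 0.147 for inflammatory, 0.347 for stress response (median -0.02 against an upward camera sign), 0.181 for RNA interference and 0.346 for leukocyte genes. Calls made only against Parental in line I were epithelial (median 0.11, camera adjusted p = 0.0019), antigen presentation (0.16, 0.0157) and ERK response genes (0.12, 0.0183) upward and p53 target genes (-0.14, 0.0306) downward. None of these passed with an estimated correlation (camera adjusted p = 0.0904, 0.409, 0.376 and 0.409). Antigen presentation and ERK response genes had a downward camera sign in line I against Mock, without a call (adjusted p = 0.45 and 0.875). For ERK response genes the median there was -0.02 and the mean 0.05.

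In line II the downward calls against Mock were also made against Parental for the mitotic (camera adjusted p = 4.74e-05), p53 (7.06e-05), interferon-stimulated (0.0417), TGF-beta (0.0288), NF-kappaB (0.000948) and cholesterol lists (8.05e-08). Of these, the cholesterol list alone passed with an estimated correlation (adjusted p = 0.0225). Part of its fall against Parental was again present in Mock, with a list mean of -0.256 in Mock against Parental and -0.143 in line II against Mock. Class I antigen presentation genes had 4 of 17 down and none up, with 4 and 1 adjusted over the list alone, and did not pass (median -0.07, camera adjusted p = 0.0951). DNA replication (0.2), ERK response (0.2) and epithelial genes (0.46) did not pass either. Invasion and adhesion genes passed downward against Parental (median -0.05, camera adjusted p = 0.0492) but not with an estimated correlation (0.26).

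Lists without a camera call in either line also held genes that changed in both. Over all genes, 2925 of 19775 did so, and such members alone therefore do not set a list apart. Of 31 drug efflux and metabolism genes, 5 rose and 6 fell in both lines, with ALDH1A3 at 1.45 and 1.38 and the efflux pump gene ABCB1 at -1.03 and -0.95 in lines I and II (camera adjusted p = 0.472 and 0.805). Adjusted over the list alone this list had 10 up and 6 down in line I and 8 up and 10 down in line II. Of 32 Notch pathway genes 2 rose and 5 fell in both lines, with MAML2 at 0.74 and 0.83 (camera adjusted p = 0.745 and 0.473), and the counts adjusted over the list alone were 2 up and 6 down in line I and 4 up and 10 down in line II. In line I this list had a median of 0.04 but a mean of -0.01 and a downward test. Of 30 angiogenesis factors 3 rose and 2 fell in both lines, with the growth factor PDGFC at -0.57 and -1.51 (camera adjusted p = 0.201 and 0.674), and 6 up and 2 down in line I and 9 up and 7 down in line II adjusted over the list alone. Of 28 mesenchymal markers 1 rose and 1, ZEB1, fell in both lines, by -0.30 and -0.42 (camera adjusted p = 0.412 and 0.258), and 1 up and 1 down in line I and 4 up and 1 down in line II adjusted over the list alone.

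Mock against Parental compares the pool of clones with the scrambled shRNA with untransfected cells, both without a CXCR4 shRNA. Transfection, shRNA, selection, clonal composition and culture history change together in this comparison. SHISA3 rose by 3.88 (SE 0.08, limma adjusted p = 7.26e-12, n = 3 arrays per group), and the receptor tyrosine kinase KIT fell by 2.97 (SE 0.11, limma adjusted p = 1.22e-09). LRCH2 (3.15), EEF1A2 (2.61), NOSTRIN (2.44), SAGE1 (2.09), TOX3 (1.96), FREM2 (1.76) and CRACDL (1.73) also rose. BCL2L15 (-2.81), NIBAN1 (-2.67), PNOC (-2.50), PDGFC (-2.31), ITGB8 (-2.18), CAV2 (-1.95) and KCNJ16 (-1.94) fell. In total 2968 genes passed, 1934 up and 1034 down, and 103 changed at least 2-fold, 36 up and 67 down. The count of 103 was 58 at a mean log2 of at least 6. The share up was 65.2% as deposited, 54.8% after quantile normalization and 75.2% after centring. Of the 103 genes, 62 were past the test the other way in both lines against Mock. Among genes shared by the lines, Mock against Parental passed the test the other way for 1105 of 2925 and for 63 of the 94 at least 2-fold. Fold changes of line I against Mock and of Mock against Parental correlated across genes at r = -0.512, where the shared Mock arrays alone gave -0.4998 in simulation. The covariance was -0.0306 against a simulated -0.00401.

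The cholesterol synthesis list fell in Mock against Parental, with 8 of 18 genes down and 1 up, the same adjusted over the list alone, and INSIG1 at -1.06 (camera adjusted p = 0.000314, and adjusted p = 0.135 with an estimated correlation). Class I antigen presentation genes rose, 8 of 17 and none down, the same adjusted over the list alone, with PSMB9 at 0.86 (camera adjusted p = 0.000595, and adjusted p = 0.29 with an estimated correlation). Hypoxia and glycolysis genes had 12 of 31 up and 2 down, with 15 and 2 adjusted over the list alone, and PDK1 at 0.65 (camera adjusted p = 0.000788, and adjusted p = 0.24 with an estimated correlation). PDK1 was 0.20 (limma adjusted p = 0.0572) with the mean of its probe sets. Stress response genes had 11 of 25 down and 2 up, with 12 and 2 adjusted over the list alone, and CTH at -0.91 (camera adjusted p = 0.000788, and adjusted p = 0.29 with an estimated correlation). ERK response genes had 12 of 25 up and 3 down, with 13 and 3 adjusted over the list alone, although EPHA4 fell by 1.71 (camera adjusted p = 0.00434, and adjusted p = 0.29 with an estimated correlation). DNA replication genes had 8 of 30 up and 1 down, the same adjusted over the list alone (camera adjusted p = 0.0355, and adjusted p = 0.29 with an estimated correlation). The 20 ribosomal protein genes had a median of 0.08 with no gene past limma's test, over all genes or adjusted over the list alone (camera adjusted p = 0.0405, and adjusted p = 0.405 with an estimated correlation). The DNA replication call ended under quantile normalization (adjusted p = 0.232) and without Parental replicate 1 (0.0763) or Mock replicate 2 (0.1). The ribosomal call ended without line I replicate 2 (0.05), Parental replicate 1 (0.0766) or 3 (0.0597), or Mock replicate 2 (0.1) or 3 (0.067), and with a replicate block (0.054). Leaving out _x_at and _s_at probe sets ended the DNA replication (0.0964) and ribosomal calls (0.341). A mean log2 of at least 6, which tests fewer genes, ended the calls for antigen presentation (0.07), hypoxia (0.114), ERK response (0.07), DNA replication (0.448) and ribosomal genes (0.359), and the upper 50% those for hypoxia (0.0503), ERK response (0.0602), DNA replication (0.342) and ribosomal genes (0.301). HES1 rose by 0.74 (limma adjusted p = 0.00355) on its _s_at probe set and was 0.04 without such probe sets.

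Line I against line II tests the difference between the knockdown lines, in which the Mock arrays cancel. The chemokine genes CXCL8 and CXCL1 were higher in line I, by 1.63 (SE 0.06, limma adjusted p = 8.01e-09, n = 3 arrays per group) and 1.58 (SE 0.13, limma adjusted p = 7.01e-06). So were SLPI (1.67), SCEL (1.62), LEMD1 (1.69), TCIM (1.55), PLAU (1.48) and SELENOP (1.84). SELENOP was 0.13 (limma adjusted p = 0.601) without _x_at and _s_at probe sets. LPAR3, a receptor for lysophosphatidic acid, was lower in line I by -1.08 (SE 0.10, limma adjusted p = 2.11e-05), as were TOGARAM2 (-0.92), MEOX1 (-0.90), SLC9A2 (-0.83), CKB (-0.79), SYBU (-0.76), MFAP2 (-0.69) and VASH2 (-0.68). In total 1413 genes differed, 922 higher and 491 lower in line I, and 39 of them at least 2-fold, 38 higher and 1, LPAR3, lower. The count of 39 was 23 with the mean of a gene's probe sets, and 17 at a mean log2 of at least 6 and 25 in the upper 50%, which test fewer genes. The count of 1413 was 865 without _x_at and _s_at probe sets, 735 in a fit of only the groups compared and 2149 with array weights. It was 770 without line I replicate 1, 789 without line I replicate 2, 914 without line I replicate 3 and 879 without line II replicate 2.

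Mitotic genes were lower in line I than in line II, 24 of 30 with none higher, and 29 adjusted over the list alone (median -0.34, camera adjusted p = 2.16e-27, and adjusted p = 0.0049 with an estimated correlation). DNA replication genes were lower too, 11 of 30 with none higher, and 16 adjusted over the list alone (median -0.18, camera adjusted p = 5.19e-11, and adjusted p = 0.0049 with an estimated correlation). The mean log2 value over the mitotic list was 9.06 ± 0.01 in Parental, 9.12 ± 0.03 in Mock, 8.56 ± 0.02 in line I and 8.91 ± 0.05 in line II (SD, n = 3 arrays). Epithelial markers were higher in line I, 11 of 27 with none lower, and 17 adjusted over the list alone (camera adjusted p = 3.81e-11, and adjusted p = 0.0049 with an estimated correlation), with MUC1 at 0.98 and CDH1 at 0.97. Class I antigen presentation genes had 11 of 17 higher, and 13 adjusted over the list alone (camera adjusted p = 1.15e-09, and adjusted p = 0.0374 with an estimated correlation). Invasion and adhesion genes had 15 of 35 higher, and 16 adjusted over the list alone (camera adjusted p = 2.32e-08, and adjusted p = 0.00745 with an estimated correlation). ERK response genes had 10 of 25 higher and 1 lower, with 12 and 2 adjusted over the list alone (camera adjusted p = 2.44e-07, and adjusted p = 0.0256 with an estimated correlation), led by PHLDA1 at 1.32. Interferon-stimulated genes had 12 of 35 higher and 1 lower, with 13 and 1 adjusted over the list alone (camera adjusted p = 4.36e-06, and adjusted p = 0.0049 with an estimated correlation), led by RSAD2 at 0.80.

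Smaller list differences between the lines were also past camera. Inflammatory genes had 5 of 25 higher in line I, also adjusted over the list alone (adjusted p = 0.00967, and adjusted p = 0.0374 with an estimated correlation). NF-kappaB target genes had 3 of 18 higher, and 4 adjusted over the list alone (adjusted p = 0.00992, and adjusted p = 0.139 with an estimated correlation). Stress response genes had 8 of 25 higher, with 9 higher and 1 lower adjusted over the list alone (adjusted p = 0.00967, and adjusted p = 0.313 with an estimated correlation). Of 22 p53 target genes 5 were higher and 1 lower, with 7 and 1 adjusted over the list alone (adjusted p = 0.0164, and adjusted p = 0.363 with an estimated correlation). Of these limma camera calls, the inflammatory one ended without line II replicate 3 (0.057), without _x_at and _s_at probe sets (0.136) and with array weights (0.0564). The stress response call ended without line II replicate 1 (0.0666), without _x_at and _s_at probe sets (0.123) and under both filters on dim genes (0.0742 and 0.0886). The NF-kappaB call ended in the upper 50% by mean log2 (0.0633) and turned downward without _x_at and _s_at probe sets (0.895). The p53 call ended without line I replicate 2 (0.066) or line II replicate 1 (0.0913), under quantile normalization (0.078) and under both filters on dim genes (0.0742 and 0.0712).

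**Figure D5:**
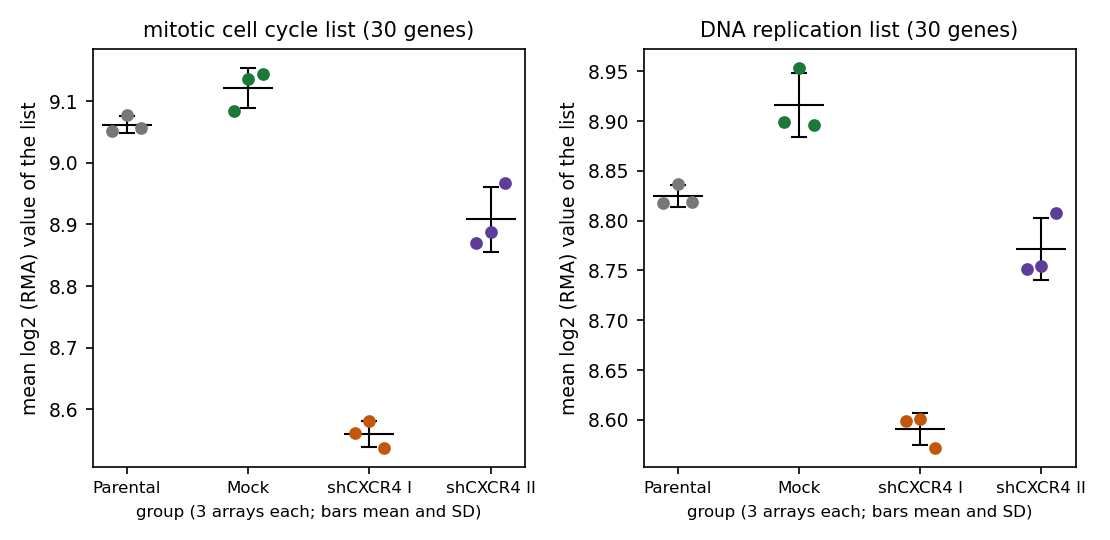
Mean log2 value of the mitotic list and of the DNA replication list (30 genes each, vertical axes) on each array by group, with bars for the mean and SD of 3 arrays. Line I lies lowest on both lists, at 8.56 and 8.59, and line II lies between it and Mock, at 8.91 against 9.12 and at 8.77 against 8.92.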

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

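In this part, 2 tests were chosen only after the result was seen: the change of the 94 2-fold genes against Parental, and the DNA replication list across array pairs. The other tests were set before their own values were seen, but after a first look at the data.

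The 2925 genes that changed in the same direction in both lines against Mock had a median change of 0.37 in that direction against Mock and of 0.185 against Parental (0.19 in line I and 0.182 in line II). A shift of the Mock pool and a change in the lines cannot be told apart for this full set, since 0.185 is 49.9% of the median against Mock (47.5% to 52.8% with 1 array left out), on both sides of the 50% above which a Mock shift was to count as excluded, although each line taken alone lay above it (52.4% and 50.5%), and 60.6% of the genes stayed past the test after quantile normalization, which leaves normalization open in part. For the 94 genes changed at least 2-fold the medians were 1.554 against Mock and 0.866 against Parental, which argues against a Mock shift as the whole cause for the set. A Mock shift as part of the cause stays open. Mock against Parental passed the test the other way for 63 of the 94, and 13 passed against Parental in the shared direction in neither line. An effect in proportion to CXCR4 loss would need larger changes in line II, where the fall of CXCR4 was 1.314 times that of line I (1.237 to 1.356 with 1 array left out, 1.228 and 1.163 on the other probe sets), but the slope of line II on line I was 1.008 (0.995 to 1.036 with 1 array left out) and 48.8% of the genes changed more in line II. Both lines are set against the same Mock arrays, and a Mock shift, left open above, would add equally to both and pull the slope toward 1. The slope therefore cannot decide for or against proportion to CXCR4 loss. CXCR4 also differed between the lines on only 1 of 3 probe sets. Clonal origin stays open and untested because both lines are clones and Mock is a pool.

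The mitotic list was lower in line I than in line II by a median of -0.343. Without line II replicate 1, which lay apart from the other arrays on the third principal component, the median was -0.377. That array had the lowest mitotic list mean of line II (8.87, against 8.887 and 8.968 in replicates 2 and 3). Leaving it out could therefore not narrow the gap in that mean, and the value of -0.377 cannot decide whether 1 array carries the difference. Each line II array did lie above every line I array (8.537 to 8.58) in that mean. After quantile normalization the median was -0.364 and after centring -0.33, which argues against the normalization as the cause. Slower division of line I is a candidate explanation that these data cannot test. The DNA replication list, which shares no gene with the mitotic list, was lower in line I in 9 of the 9 pairs of arrays. That list was already known to be lower in line I, and the pairs reuse the same arrays. The pairs therefore restate that result and give no separate support for slower division. Growth rates are not given in the sources used here, and an effect of the shRNA sequence, of the clone or of culture density stays open and untested.

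For comparisons of 3 arrays against 3, fitted on those 6 arrays alone, 10 splits exist, too few for a share under 0.05. In line I against Mock 1 split, the real one, gave as many genes (4548, highest other 0) and 1 as many lists (9, highest other 6). The same was true of line II against Mock, with 3027 genes (highest other 0) and 10 lists (highest other 4), of Mock against Parental, with 2653 genes (0) and 7 lists (4), and of line I against line II, with 735 genes (0) and 11 lists (5). For both lines against Mock, 1 of 100 splits of the 9 arrays into 3 groups, the real one, gave as many shared genes (2404, highest other 1723). For both lines against both controls 1 of 100 splits of the 12 arrays, the real one, gave as many (907, highest other 5). A random assignment of arrays to groups therefore does not account for the counts of both lines together, against Mock or against both controls. The 10 splits of 6 arrays are too few to decide this for the single comparisons. Every other split mixed arrays of different groups, however, and arrays of a group are alike. Differences between clones, or of the Mock pool, stay within the real grouping, so these splits cannot exclude them.

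The effects of the shRNA lines against Mock differed from each other by limma's test of line I minus line II for 68 of the 164 named genes, 45 higher and 23 lower in line I, and by camera for 11 of 27 lists. The naming rule takes genes in part for a large difference between the lines, so the share of named genes does not describe genes in general. Over all genes, 1413 of 19775 (7.1%) differed. The differences of the named genes and lists are all given here as log2 line I minus line II, and none is explained. Among genes of the CXCR4 axis, chemokines and NF-kappaB target genes the differences were CXCR4 0.468, RGS2 0.381, CXCL8 1.628, CXCL1 1.576 and TNFAIP3 0.344. Among genes leading in the single comparisons they were SELENOP 1.84, LEMD1 1.687, SLPI 1.67, SCEL 1.624, TCIM 1.55, PLAU 1.48, KCTD12 1.317, KCNJ16 1.289, THSD7A 1.208, PDGFC 0.94, LGALS3 0.828, UNC93A 0.774, SCGB2A1 0.671, CRACDL 0.667 and ITGB8 0.421. Those lower in line I were LPAR3 -1.076, TOGARAM2 -0.915, MEOX1 -0.9, SLC9A2 -0.829, CKB -0.794, SYBU -0.764, MFAP2 -0.692, VASH2 -0.677, STK32B -0.6, SAMD5 -0.435, PNOC -0.393, BCL2L15 -0.364 and GJA1 -0.31. Interferon and antigen presentation genes gave RSAD2 0.804, ERAP2 0.482, IFITM1 0.397, TAP2 0.388 and PSMB9 0.374. Epithelial and ovarian lineage genes gave MUC1 0.981, CDH1 0.971, MSLN 0.633, KRT7 0.325 and JUP 0.251. The fibroblast marker MFAP5 gave 0.609 and the X-linked cancer-testis antigen list member PRAME 0.318. Signalling genes gave PHLDA1 1.32, SOX9 1.057, PLK2 0.657, SPRY2 0.653, SKIL 0.609, TGFA 0.564, ADAM10 0.249, EPHA4 -0.256 and ID3 -0.439. Metabolic and stress genes gave UGT1A6 0.494, SLC7A11 0.452, CTH 0.381, SLC2A1 0.326, ASNS 0.303 and MXI1 0.283. Cell cycle genes gave CDCA8 -0.594, PTTG1 -0.484, MCM7 -0.408, RRM2 -0.388, CENPE -0.363, NUSAP1 -0.316, ORC1 -0.3 and MCM5 -0.292. The list medians were mitotic -0.343, DNA replication -0.182, antigen presentation 0.281, epithelial 0.201, ERK response 0.193, invasion and adhesion 0.182, interferon-stimulated 0.114, stress response 0.094, NF-kappaB 0.072, p53 0.063 and inflammatory 0.042.

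Leaving out 1 array ended the call between the lines for 16 of 67 named genes other than CXCR4: ADAM10, CTH, EPHA4, GJA1, JUP, KRT7, MCM5, MXI1, NUSAP1, ORC1, PRAME, PSMB9, RGS2, TAP2, TNFAIP3 and UGT1A6. Without line I replicate 1, 11 calls ended (limma adjusted p 0.0607 to 0.192), without replicate 2, 12 (0.0545 to 0.178), and without replicate 3, 9 (0.0526 to 0.175). Without line II replicate 1, 9 ended (0.0534 to 0.136), without replicate 2, 12 (0.054 to 0.155), and without replicate 3, 3 (0.0843 to 0.116). Parental replicates 1, 2 and 3 ended 4 (0.0594 to 0.0703), 5 (0.0502 to 0.0655) and 5 (0.0535 to 0.067), and Mock replicates 1 and 2 ended 3 (0.0502 to 0.061) and 1 (0.0629).

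Other alternatives also ended calls between the lines, with these values of line I minus line II. With the mean of a gene's probe sets they were BCL2L15 (-0.182), SAMD5 (-0.2), ITGB8 (0.071), TAP2 (0.139), ADAM10 (0.169), KRT7 (0.166), EPHA4 (-0.183) and ASNS (0.145). Without _x_at and _s_at probe sets they were LGALS3 (0.005), SELENOP (0.134), SLC2A1 (0.118), RRM2 (-0.132), KRT7 (0.123) and ASNS (-0.012), and GJA1, MXI1 and EPHA4 with unchanged values (adjusted p = 0.0609, 0.0571 and 0.0532). Quantile normalization ended the calls for GJA1 (-0.29), ADAM10 (0.214) and MXI1 (0.253), and centring those for GJA1 (-0.297) and JUP (0.264). A fit of only the groups compared, which leaves the values as they are, ended those for GJA1, PSMB9, ADAM10, MXI1, NUSAP1, MCM5, ORC1, JUP, EPHA4, CTH and UGT1A6 (limma adjusted p 0.0514 to 0.124). A replicate block ended those for MXI1 (0.0529) and JUP (0.0564).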

How the results depend on the processing

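All alternatives here were planned before the data were examined, other than Parental in place of Mock for the gene lists, which was chosen after seeing the data, and the cause was not tested where none is named. The CXCR4 falls in both lines kept their direction and passed under every alternative run. For shared genes at least 2-fold, all 94 kept their direction and passed wherever all were tested, while 81, 46 and 62 were tested without _x_at and _s_at probe sets, at a mean log2 of at least 6 and in the upper 50%, and 73, 46 and 62 passed. Of calls on named genes other than CXCR4, 101 of 134 in line I against Mock, 93 of 132 in line II against Mock, 75 of 104 in Mock against Parental and 43 of 67 in line I against line II held at the same threshold, with no minimum fold, in every alternative that tested the gene. Of these, 43, 45, 31 and 18 were tested in all. Named genes were chosen largely for large changes, so these shares do not describe calls in general. Of the 2925 shared genes, single alternatives of this kind that tested all of them kept 60.6% (quantile normalization) to 95.1% (trended and robust variance). With an estimated correlation, list counts were 2 in line I against Mock, 0 in line II against Mock, 0 in Mock against Parental and 2 for the mean of the lines against Mock; fry gave 17, 17, 19 and 18, and turned Wnt target genes in Mock against Parental upward (median -0.057). Where camera with an estimated correlation gave 0, its unadjusted p was under 0.05 for 9 lists in line II and 4 in Mock. All probe sets, which test more items, gave 7770 (287 at least 2-fold) in line I against Mock, 8866 (271) in line II against Mock, 193 at least 2-fold in Mock against Parental, and 4560 (175) in both lines, 60 against both controls; CXCR4 between the lines was 0.256 and 0.174 on its other probe sets and no longer passed. The mean of a gene's probe sets gave 2-fold counts of 95 (line I), 101 (line II), 23 (between the lines), 62 (both lines) and 18 (both controls). Without _x_at and _s_at probe sets, 865 genes differed between the lines, 568 passed against both controls and 5 lists in line I, and signs turned for KRT7 (0.173 in line I, 0.051 in line II, -0.043 in Mock), SMAD6 (0.001, 0.064, -0.132), COL6A1 (0.106, 0.295, -0.115), CCND1 (0.092 in line I), LGALS3 (-0.1) and SELENOP (0.122) in Mock against Parental, ASNS (-0.012) and the NF-kappaB list (-0.004) between the lines. At a mean log2 of at least 6, which tests fewer genes, 2-fold counts were 75 (line I), 78 (line II), 58 (Mock), 17 (between the lines), 46 (both lines) and 12 (both controls), with 5, 2 and 6 lists in line II, Mock and the mean of the lines. In the upper 50% they were 25 between the lines, 62 and 20, with 6, 4 and 6 lists. Quantile normalization left 5 lists for the mean of the lines. CXCR4 in Mock against Parental now passed with the mean of probe sets (0.304), both dim filters, the trended variance and only the groups compared (0.251 each), centring (0.291) and array weights (0.252). Array weights gave 2149 genes between the lines. Only the groups compared gave 3027 in line II and 735 between the lines. A minimum fold of 1.2 gave 720, 592, 432, 127, 355 and 128 (line I, line II, Mock, between the lines, both lines, both controls), and CXCR4 between the lines (0.468) no longer passed. Adjusted p under 0.01 gave 2589, 2579, 1585, 589, 1456 and 459, with 5 lists for the mean of the lines. Parental in place of Mock gave 3353 genes in line II and 7 lists in each line, and turned camera's sign in line I upward for 3 lists with a call against Mock or Parental, hypoxia (median 0.009, no call against Parental), antigen presentation (0.163) and ERK response (0.125), while the stress response median (-0.019) turned without its sign. Replicate numbers did not pair the arrays: same-number pairs correlated at -0.109 to 0.148 after removing group means, against -0.228 to 0.234 for other pairs, and a replicate block gave 4549, 5013, 2771 and 1215 genes in line I, line II, Mock and between the lines.

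Leaving out each array gave 3314 to 5184 genes in line I against Mock (148 to 154 at least 2-fold), 3667 to 6070 (150 to 159) in line II, 2079 to 3308 (101 to 110) in Mock against Parental, 770 to 1799 (32 to 42) between the lines, 2080 to 3194 (91 to 99) in both lines and 643 to 998 (33 to 37) against both controls. CXCR4 had -1.527 to -1.464, -2.023 to -1.845, 0.223 to 0.294 and 0.354 to 0.531 in the first 4 of these. Lists past the test numbered 7 to 11, 10 to 12, 5 to 7, 9 to 12 and, for the mean of the lines, 8 to 11 (10 with all arrays). Between the lines the count was 770, 789 and 914 without line I replicates 1, 2 and 3 and 879 without line II replicate 2. Signal over background can limit dim genes, which was not tested. The smallest simulated change was recovered for 44% of the changed genes in line I against Mock. As far fewer genes changed in the simulation than passed in the data, this share does not carry over to the data.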
